A study of Mus musculus with 24 samples.

How the data were processed

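Sox9-lineage (tdTomato-positive) cells were sorted from kidneys 48 h and 10 days after bilateral ischaemia-reperfusion injury, fixed lightly, frozen and divided into aliquots for CUT&RUN with a Sox9 antibody, an H3K4me3 antibody or as input, per the labels' protocols. Of 24 samples, the 16 antibody libraries had a peak list each, called per library against the input of the same pellet, per the peak names in the files. The input libraries were not analysed here. Per the submitters' processing notes, Partek 10, Bowtie2, Bowtie and MACS3 were used with the mm10 genome; read filters, treatment of duplicates, scaling of antibody to input and the peak threshold were not given in the sources used here. Depth per library was not given, so precision rests on the 4 replicates per group.

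Each deposited list gives positions, a score, a fold and 2 significance values per peak. The fold enrichment is the authors' ratio of antibody pileup over local background at the summit. The p-value and q-value were deposited as −log10 values by the authors' caller and are not comparable between lists. The deposited score column is a whole-number display score and was not used. The fold and the 2 significance values were used only within a list, to rank or filter peaks and to solve the pileup. Under the assumption that the fold has 1 added to pileup and background and that the p-value is a Poisson tail, the pileup and background of each peak were solved from both. Between 99.9871% and 99.9989% of the peaks of a list could be solved. Of these, 99.9898% to 100% had a pileup within 0.05 of a whole multiple of 1 step (60.1 to 508 between lists), and 0 peaks lay between 1 and 2 steps.

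Peaks on chromosomes 1 to 19, X and Y were used. Gene positions were taken from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes. The table gives no strand, so the planned window around transcription start sites was replaced by 1000 bp around either end of a gene, which also takes in the 3′ end. No genome sequence was used, so the planned count of Sox motifs at summits was not run. Shifted summits were moved along their chromosome by multiples of 500000 bp, 10 times. Regions were the merged peaks of the 8 lists of an antibody, and 1 bp of overlap counted as presence. A region or gene was specific to a time with a peak in 4 of 4 libraries of it and 0 of 4 of the other.

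The tests, the 25 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were 10 genes of tubule injury and Sox9 biology, and, ranked by the mean within-library percentile of fold, up to 8 genes of each direction specific to a time, up to 8 with a Sox9 peak in 8 of 8 libraries and up to 5 regions of each kind. Of each list that passed a test, the 4 members with a peak in the most libraries were named, ties being ordered by that percentile. Among the 1-step peaks of a list the fold differs only by local background, so there this percentile ranks low background and not height. The same holds for p, so equal list lengths by p favour low background among these peaks. Times were compared by two-sided exact permutation of 4 against 4 libraries, lists within a time by Fisher's exact test on genes with a peak in at least 3 of 4 libraries, and peak sets by base-pair Jaccard index over 35 splits. Gene-list odds ratios had 0.5 added to each cell and were adjusted by the Benjamini-Hochberg method; genes are not independent replicates. The comparison of mean log2 odds ratios over 8 libraries with 10000 random gene lists was added after the data were seen. It replaced sign flips of the same values, tried first, because adding 0.5 raises the ratio where few genes have a peak; which lists pass depends on which of these tests is used. The ratios over shifted peaks and the comparison of lists within pellets were also added then.

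Sox9 and H3K4me3 libraries with the same time and number came from 1 pellet, per the labels' protocols, and were paired on that ground. In peaks at gene ends, their deviations from the group means correlated between -0.0062 and 0.0195 at 10 days and between -0.00079 and 0.00483 at 48 h. The best match was the pellet's own partner for 1 of 4 at 10 days and 0 of 4 at 48 h. The pairing therefore rests on the labels alone. The replicates were labelled as biological. At most 13 peaks had the same start and end in any pair of lists of an antibody, so no list was a copy of another.

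Alternatives were a q-value filter (−log10 of at least 5), equal list lengths by p or at random, 2 or more steps, a 3000 bp window, the gene body with 10000 bp, other presence rules, other backgrounds, a replicate block, removal of recurrent genes and leaving out replicates. Random equal numbers were 1 draw from each list, except for 20 draws of H3K4me3 genes specific to a time. The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. On simulated data the step number was recovered for 100% of peaks. Of 200 genes planted in 4 of 4 10-day lists, 75.5% were recovered in Sox9 and 63.5% in H3K4me3 lists, the rest being hidden by background peaks at 48 h. With detection of 90 percent in each list, 53.5% and 44% were recovered. With none planted, peaks dealt at random to lists of the real lengths gave 3 and 50 genes specific to a time among 21887. Lists of 24 genes without an effect had p under 0.05 against random lists in 5% (Sox9) and 4.5% (H3K4me3) of 200 simulations. This follows by construction, since both kinds of list were drawn at random from the same genes. The random lists were matched for number of genes only, not for gene length. Between times, lists with 30% of genes added at 10 days reached an unadjusted p under 0.05 in 55.5% and 59.5%.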

Results

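CUT&RUN, in which an antibody guides a nuclease to cleave the DNA around a bound protein, was used to map Sox9 and H3K4me3 in mouse kidney cells after injury. Sox9 is a transcription factor that is switched on in injured tubules. H3K4me3, a histone mark of active promoters, was the positive control of the protocol. The cells came from male mice with a tamoxifen-inducible Cre recombinase at the Sox9 locus and a tdTomato reporter, so that cells with Sox9 activity at the time of bilateral ischaemia-reperfusion injury, and their descendants, were red and could be sorted. Cells were collected 48 h or 10 days after injury (4 biological replicates at each time), and each frozen pellet was divided between Sox9, H3K4me3 and an input. The times come from the sample titles, because the cell type label names day 10 for every sample, including those titled 48 h. There were 16 peak lists, 1 for each Sox9 and H3K4me3 library. The 8 inputs were not analysed here as separate samples. Sequencing depth is unknown.

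The Sox9 lists held 7724 to 85420 peaks and the H3K4me3 lists 25824 to 88511. On chromosomes 1 to 19, X and Y, Sox9 had 39320 ± 32699 peaks (SD, n = 4) at 10 days and 16760 ± 7700 (SD, n = 4) at 48 h. H3K4me3 had 56545 ± 29316 peaks (SD, n = 4) at 10 days and 31455 ± 4902 (SD, n = 4) at 48 h. The mean log2 difference between the times was 1.00 for Sox9 and 0.70 for H3K4me3, and neither passed (two-sided exact permutation tests, p = 0.229 and p = 0.2). Without 10d replicate 1 the differences were 0.50 and 0.43. With 70 arrangements of 4 against 4 libraries the smallest p such a test can give is 0.0286. In every list the heights of nearly all peaks (lowest 99.9898% of those solved) were whole multiples (within 0.05) of 1 list-specific step, and 92.5% to 97.7% of the peaks stood at exactly 1 step.

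**Figure D1:**
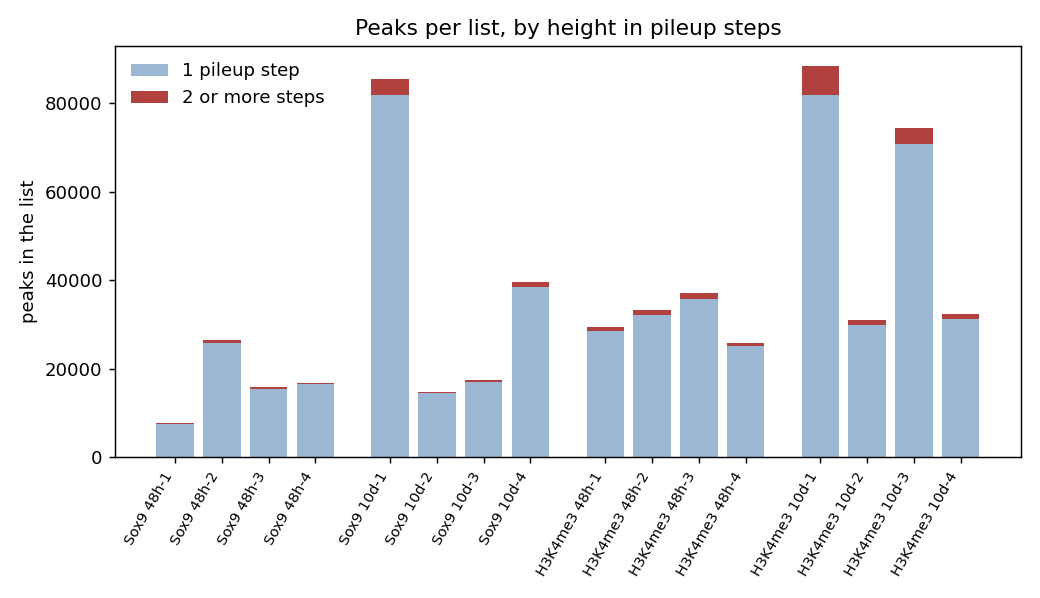
Number of peaks (vertical axis) in each of the 16 lists (horizontal axis, antibody, time and replicate). Each bar is divided into peaks at 1 pileup step and peaks of 2 or more steps; the 1-step share lies between 92.5% and 97.7% in every list.

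Sox9 and H3K4me3 peaks both lay at the ends of protein-coding genes more often than shifted peaks did. The summit was within 1000 bp of a gene end for 8.70% ± 1.67 (SD, n = 8) of Sox9 peaks and 8.56% ± 0.844 (SD, n = 8) of H3K4me3 peaks, against 3.68% and 3.67% after the same peaks were shifted along the genome. The ratio over shifted peaks was above 1 in 8 of 8 Sox9 lists (mean 2.35, range 1.58 to 2.87) and in 8 of 8 H3K4me3 lists (mean 2.34, range 2.14 to 2.93). An exact sign-flip permutation test gave p = 0.0078 for each antibody, the smallest that 8 lists can give. The Sox9 and H3K4me3 shares differed by 0.138 percentage points, less than the spread between libraries (two-sided exact permutation test, p = 0.845). Among peaks of 2 or more steps the share was 15.4% ± 4.54 (SD, n = 8) for Sox9 and 20.3% ± 9.27 (SD, n = 8) for H3K4me3. This difference did not pass either (exact permutation p = 0.206, and 0.258 when paired by pellet). H3K4me3 10d replicate 1 was at 41.8%, and without its pellet the difference of -4.92 points became -0.900.

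Between the times, the Sox9 share at gene ends was 7.92% ± 1.93 (SD, n = 4) at 10 days and 9.48% ± 1.07 (SD, n = 4) at 48 h (difference -1.56 points, two-sided exact permutation p = 0.257; -0.729 points without 10d replicate 1). The H3K4me3 share was 8.75% ± 1.18 (SD, n = 4) at 10 days and 8.37% ± 0.409 (SD, n = 4) at 48 h (difference 0.383 points, two-sided exact permutation p = 0.743; -0.201 points without 10d replicate 1). Among H3K4me3 peaks of 2 or more steps it was 23.3% at 10 days and 17.4% at 48 h (difference 5.90 points, exact permutation p = 0.6). Without 10d replicate 1 this difference was -0.271 points.

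**Figure D2:**
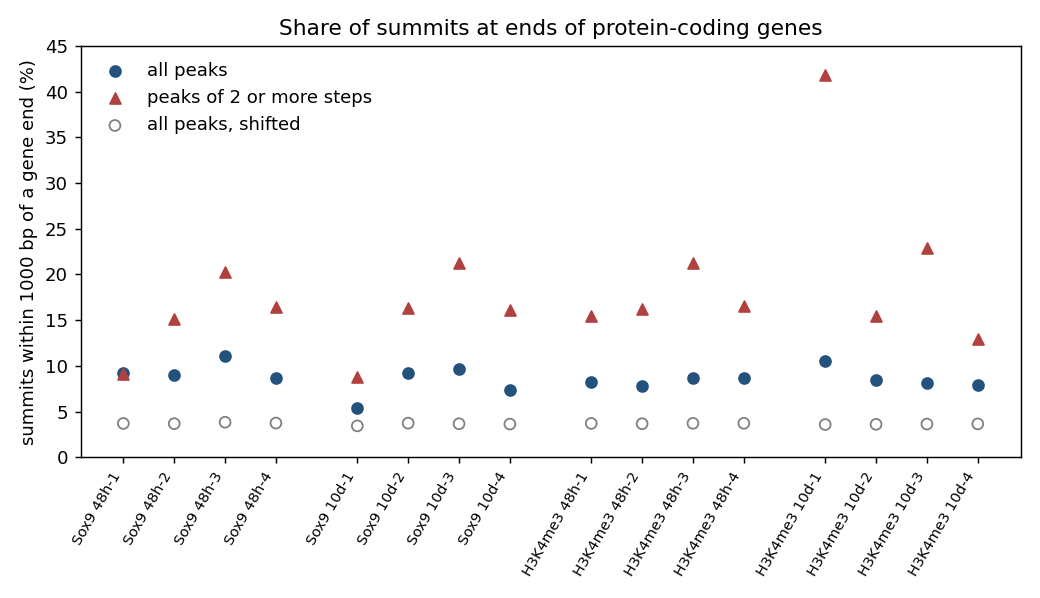
Percent of summits within 1000 bp of an end of a protein-coding gene (vertical axis) in each list (horizontal axis). Filled circles are all peaks, triangles peaks of 2 or more steps, and open circles all peaks after shifting; the filled circles lie above the open circles in all 16 lists.

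Few positions recurred between libraries of an antibody, and most of the Sox9 regions that recurred in every library had H3K4me3 peaks too. Of 215061 merged Sox9 regions 96.7% had a peak in 1 library, and of 328687 H3K4me3 regions 94.7% did. A Sox9 peak was present in 8 of 8 libraries at 39 regions, of which 35 also had an H3K4me3 peak in 8 of 8 libraries. Of the 39 regions 28 lay in no gene, and no list of regions prone to artefacts was used here to remove any. An H3K4me3 peak was present in 8 of 8 libraries at 82 regions, of which 36 had a Sox9 peak in 8 of 8 and 51 in at least 7. The 5 of these Sox9 regions with the highest rank by the authors' fold enrichment (mm10 coordinates) were chromosome 16, 89419708 to 89420050, at Krtap6-2, a keratin-associated protein gene of hair; chromosome 2, 35802097 to 35802430, within Ttll11; chromosome 8, 89755006 to 89755192, in no gene; chromosome 11, 69586946 to 69587634, at Trp53, which encodes the p53 tumour suppressor; and chromosome 5, 75170498 to 75170950, within Pdgfra, a growth factor receptor gene of stromal cells. Each of the 5 had an H3K4me3 peak in 8 of 8 libraries. A high rank by fold is not the greatest height, since it also rises with low local background. The region on chromosome 2, 98662239 to 98662974, had Sox9 peaks of 72 to 580 steps and a mean percentile of 0.872. The genes with a Sox9 peak at an end in 8 of 8 libraries were Krtap6-2, Pgk1, a glycolytic enzyme, and Rps29, a protein of the small ribosomal subunit, and the same 3 had an H3K4me3 peak in 8 of 8. The region near Rps29, chromosome 12, 69159292 to 69159594, lay outside the gene. At Pgk1 no single region had a Sox9 peak in 8 of 8. The H3K4me3 regions at its higher and lower coordinate ends had Sox9 peaks in 7 and 4 libraries. Strand was not given, so an end may be the 3′ end.

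At 10 genes of tubule injury and Sox9 biology, a Sox9 peak lay at a gene end in 12 of 80 pairs of gene and library (15%, against 9.98% over all genes) and an H3K4me3 peak in 9 of 80 (11.25%, against 17.3%). No test was made of these shares. At these ends a peak of 2 or more steps was present only at Wnt4 for Sox9 and at Lrp2 for H3K4me3, each in 1 library. Within the gene body and 10000 bp, a window that widens with gene length, the shares were 56.25% for Sox9 (43.9% over all genes) and 80% for H3K4me3 (59.9%). Sox9 peaks lay there at Wnt4 in 8 of 8 libraries, at Lrp2 in 7 and at Sox9 in 5. H3K4me3 peaks lay there at Wnt4, Lrp2 and Col2a1 in 8 of 8, and at Havcr1 and Vcam1 in 6. At gene ends, Sox9 itself (chromosome 11, 112782210 to 112787757) had a Sox9 peak in 1 of 4 libraries at 10 days and 2 of 4 at 48 h, and an H3K4me3 peak in 0 of 4 and 1 of 4. Cdh6, a cadherin of tubule progenitors, had a Sox9 peak in 1 of 4 libraries at 10 days and 0 of 4 at 48 h. Wnt4, a ligand needed for nephron formation, had one in 2 of 4 and 1 of 4, and an H3K4me3 peak also in 2 of 4 and 1 of 4. Havcr1, which encodes the injury marker kidney injury molecule, and Vcam1, an adhesion molecule, had no peak of either antibody at an end in any library. Sox9 peaks were present at Lrp2, the endocytic receptor megalin of the proximal tubule, in 1 of 4 and 0 of 4, and at Krt8, an epithelial keratin, in 1 of 4 and 0 of 4. Hnf4a, a proximal tubule transcription factor, had one in 0 of 4 and 1 of 4, Col2a1, the cartilage collagen gene bound by Sox9 in chondrocytes, in 2 of 4 and 0 of 4, and Pax8, a kidney transcription factor, in 0 of 4 at both times. H3K4me3 peaks at Lrp2, Krt8, Pax8, Hnf4a and Col2a1 were present in at most 1 of 4 libraries of either time.

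Over all 8 Sox9 libraries, genes of Wnt signalling, the Sox family, the immediate early response, the Hippo pathway and glycolysis had a peak at an end more often than random genes. The mean log2 odds ratio was 1.21 ± 0.54 (SD, n = 8, above 0 in 8 of 8 libraries) for Wnt ligands, such as Wnt4 (3 of 8 libraries), Wnt1 (3 of 8), Wnt7a (3 of 8) and Wnt5b (2 of 8). It was 1.08 ± 0.18 (SD, n = 8, 8 of 8) for Wnt receptors and targets, including Wls, which carries Wnt ligands to the cell surface (7 of 8), the Frizzled receptors Fzd4 and Fzd8 (4 of 8 each) and Ctnnb1, the gene of beta-catenin (3 of 8). A region with a Sox9 peak in 7 libraries, chromosome 3, 159939410 to 159939679, lay outside Wls, beyond its higher coordinate (159938666). The Sox family reached 1.23 ± 1.11 (SD, n = 8, 7 of 8), with Sox8 in 4 of 8 libraries and Sox9, Sox3 and Sox11 in 3 of 8 each. Immediate early and stress genes reached 1.07 ± 0.58 (SD, n = 8, 8 of 8), with Egr1 in 4 of 8, Jund and the heat shock gene Hspa1b in 3 of 8 each, and Fosb in 2 of 8. Hippo pathway genes reached 1.08 ± 0.64 (SD, n = 8, 8 of 8), with the coactivator gene Yap1 in 5 of 8 and Lats2, Tead3 and Lats1 in 3 of 8 each. Hypoxia and glycolysis genes reached 1.08 ± 0.47 (SD, n = 8, 8 of 8), with Pgk1 in 8 of 8 and Pfkp, Epas1 and Adm in 2 of 8 each. Of the members named here, Pgk1 had a Sox9 peak of 2 or more steps in 8 libraries, Wls in 6, Yap1 in 5, and Wnt4 and Wnt1 in 1 each. All the other named members had only 1-step Sox9 peaks at their ends. Against 10000 random gene lists of the same size, a permutation test chosen after the data were seen, the adjusted p was 0.01 for Wnt receptors and targets and 0.0308 for each of the other 5 lists (Benjamini-Hochberg over 25 lists). Without the 29 genes that had a peak in 7 or more libraries of an antibody, Wls, Yap1 and Pgk1 among them, 1 Sox9 list passed (Wnt ligands, adjusted p = 0.05 by the same permutation, rounded from just below the threshold). The mean log2 odds ratio (SD, n = 8) of Wnt ligands was then 1.22 ± 0.54. That of immediate early and stress genes was 1.08 ± 0.58 and that of Wnt receptors and targets 0.85 ± 0.33 (adjusted permutation p = 0.055 for each of these). It was 1.04 ± 1.35 for the Sox family (adjusted permutation p = 0.115), 0.88 ± 0.76 for the Hippo pathway (0.156) and 0.61 ± 0.52 for hypoxia and glycolysis (0.355). Without Sox9 10d replicate 1 hypoxia and glycolysis were at 1.03 ± 0.48 (SD, n = 7) and did not pass (adjusted permutation p = 0.101). In 1 random draw of equal numbers of peaks from each library, not repeated, 0 lists passed (adjusted permutation p from 0.0725 to 0.24 for these 6). Their mean log2 odds ratios were still 1.15 for Wnt ligands, 1.18 for Wnt receptors and targets and 1.66 for the Sox family. Immediate early and stress genes were at 1.21, the Hippo pathway at 1.22 and hypoxia and glycolysis at 1.41 (SD from 0.44 to 1.13 over the 6, n = 8). Fewer genes had a peak then. The mean of random lists rose from between 0.01 and 0.10 to between 0.15 and 0.51 with the 0.5 added to each count. With equal list lengths by p, which among 1-step peaks favours low background, 0 lists passed either (adjusted permutation p from 0.0675 to 0.907). Wnt receptors and targets were then at 0.72 against a mean of random lists of 0.63, and the Sox family at 1.24 against 1.28. Immediate early and stress genes were at 1.29 (adjusted permutation p = 0.696). Wnt ligands were at 1.76 against 1.28, the Hippo pathway at 1.80 against 1.09 and hypoxia and glycolysis at 2.48 against 1.13. Among genes with an H3K4me3 peak in at least 1 library, Wnt receptors and targets passed (0.95, adjusted permutation p = 0.02) and the other 5 did not (0.80 to 0.98, adjusted permutation p from 0.107 to 0.156). With peaks of 2 or more steps 0 lists passed as well, at 2.54 to 3.92 against means of random lists of 1.80 to 2.64 (adjusted permutation p from 0.0875 to 0.971).

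The other 19 lists did not pass for Sox9. Their mean log2 odds ratios were 0.88 for housekeeping genes, 0.82 for fatty acid oxidation, 0.79 for kidney transcription factors, 0.75 for the Notch pathway, 0.67 for endothelium, 0.67 for the p53 response, 0.35 for podocytes and parietal cells, 0.27 for fibrosis and matrix, 0.21 for cartilage targets of Sox9 and 0.08 for stroma and mural cells. They were -0.03 for cadherins, -0.09 for the cell cycle, -0.13 for the injured tubule, -0.18 for the EGF receptor pathway, -0.30 for inflammation, -0.44 for other nephron and duct segments, -0.57 for genes silent outside their tissue, -0.64 for the differentiated proximal tubule and -0.80 for immune cells.

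H3K4me3 peaks lay at genes of 4 of the same groups more often than at random genes, and each of the 4 calls ended under some alternative. The mean log2 odds ratio was 1.27 ± 0.97 (SD, n = 8, 8 of 8 libraries) for the Sox family and 0.85 ± 0.52 (SD, n = 8, 8 of 8) for Wnt receptors and targets (adjusted permutation p = 0.0117 for each). For immediate early and stress genes it was 1.33 ± 0.86 (SD, n = 4) at 10 days and 1.06 ± 0.195 (SD, n = 4) at 48 h, above 0 in 8 of 8 libraries (adjusted permutation p = 0.01 over both times). For hypoxia and glycolysis it was 1.01 ± 1.41 (SD, n = 4) at 10 days and 1.19 ± 0.61 (SD, n = 4) at 48 h, above 0 in 6 of 8 libraries (adjusted permutation p = 0.0187 over both times). The members named by rule were Sox12 (7 of 8), Sox17, Sox3 and Sox11 (4 of 8 each); Hspa1b (5 of 8), Jun, Junb and Egr1 (4 of 8 each); Pgk1 (8 of 8), Epas1 (5 of 8), Car9, a carbonic anhydrase gene, and Adm (3 of 8 each); and Wls (8 of 8), Fzd1 (6 of 8), Fzd4 and Lef1 (4 of 8 each). Without the 29 recurrent genes 1 of the 4 passed, immediate early and stress genes (adjusted permutation p = 0.005). The others were then at 1.03 ± 1.04 for the Sox family, 0.70 ± 0.56 for Wnt receptors and targets and 0.80 ± 1.18 for hypoxia and glycolysis (SD, n = 8, adjusted permutation p = 0.0967, 0.0967 and 0.135). Without H3K4me3 10d replicate 1 hypoxia and glycolysis were at 0.95 ± 1.00 (SD, n = 7) and did not pass (adjusted permutation p = 0.08). In 1 random draw of equal numbers of peaks, not repeated, immediate early and stress genes passed (1.21, adjusted permutation p = 0.035). The Sox family (1.00), Wnt receptors and targets (0.68) and hypoxia and glycolysis (1.04) did not (adjusted permutation p = 0.093, 0.093 and 0.0625). Equal list lengths by p ended the calls of immediate early and stress genes (0.88) and Wnt receptors and targets (0.68, adjusted permutation p = 0.21 for each). Peaks of 2 or more steps ended those of immediate early and stress genes (2.03 against a mean of random lists of 1.22) and the Sox family (1.97 against 1.44, adjusted permutation p = 0.168 and 0.334). Within pellets, the Sox9 and H3K4me3 odds ratios differed past the threshold for 0 of 25 lists (exact sign-flip permutation, lowest p = 0.0859, adjusted p = 0.916, for endothelium).

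**Figure D3:**
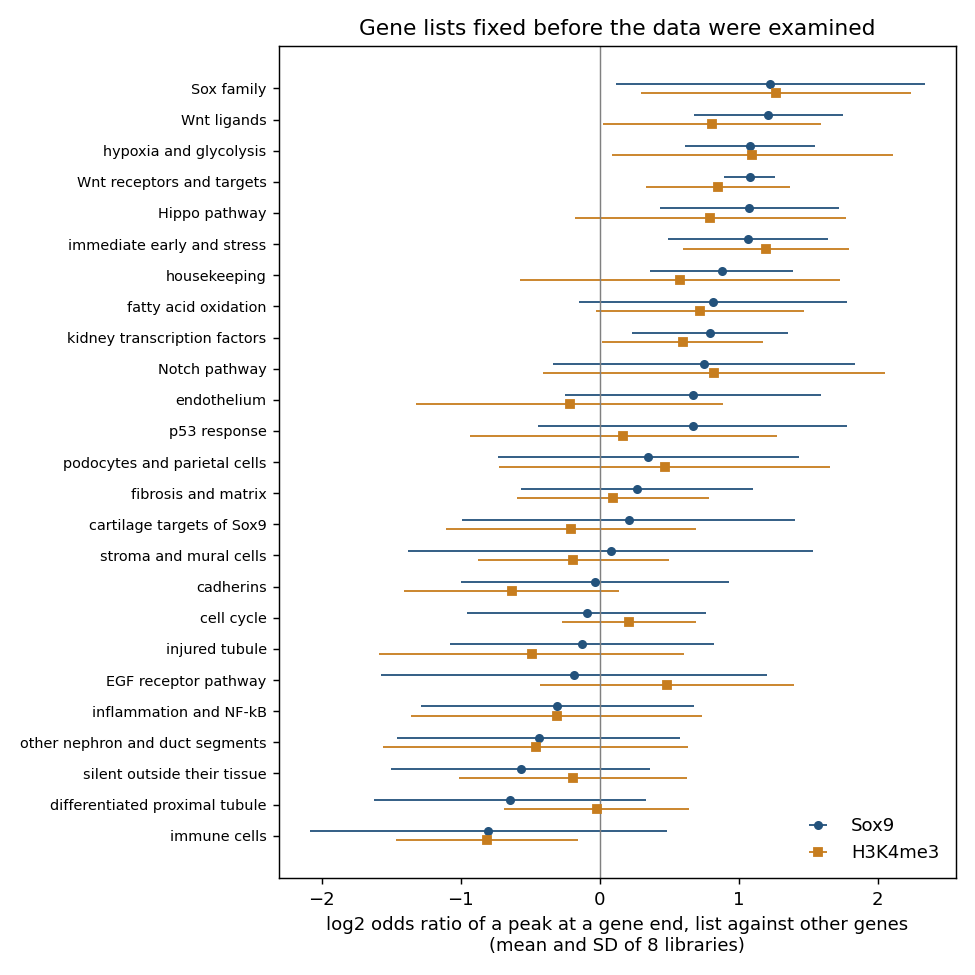
Mean log2 odds ratio of a peak at a gene end for list genes against all other protein-coding genes (horizontal axis) for the 25 gene lists (vertical axis), in Sox9 (circles) and H3K4me3 (squares) libraries; bars are the SD of 8 libraries. Wnt ligands lie at 1.21 and immune cells at -0.80 for Sox9.

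Gene groups were then compared between 48 h and 10 days, the question of the design. For Sox9 the difference was widest relative to its spread for endothelial genes, at 1.32 ± 0.80 (SD, n = 4) at 48 h and 0.02 ± 0.44 (SD, n = 4) at 10 days, and the exact permutation p of 0.0286 became 0.714 after adjustment. Notch pathway genes were at 1.52 ± 0.93 (SD, n = 4) at 48 h and -0.02 ± 0.54 (SD, n = 4) at 10 days (exact permutation p = 0.0571). For H3K4me3 the lowest exact permutation p was 0.0571 (adjusted p = 0.833), for podocyte and parietal cell genes at 1.25 ± 0.94 (SD, n = 4) at 48 h and -0.32 ± 0.88 (SD, n = 4) at 10 days. For either antibody 0 of 25 lists passed, and at an unadjusted p under 0.05 there was 1 list for Sox9 and 0 for H3K4me3. A list could pass only if at least 15 of the 25 reached the smallest p.

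Within each time, lists were tested for genes with a peak in at least 3 of 4 libraries. Sox9 had 263 such genes at 10 days and 105 at 48 h, and H3K4me3 had 1257 and 385. At 10 days an H3K4me3 peak was present at 7 of 39 Wnt receptors and targets, 5 of 23 Hippo pathway genes and 5 of 24 housekeeping genes (Fisher's exact test, p = 0.00619, 0.00876 and 0.0106, adjusted p = 0.176 for each). For Sox9 the lowest p was for housekeeping genes at 48 h, with 2 of 24 genes (Fisher's exact test, p = 0.00587, adjusted p = 0.294). For both antibodies 0 of 50 tests passed, and an unadjusted p under 0.05 was given by 3 for Sox9 and 6 for H3K4me3. Leaving out H3K4me3 10d replicate 1, 2 or 3 gave 2, 2 and 3 passing tests, where a gene needed a peak in all but 1 of the remaining libraries.

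Genes with a peak in 4 of 4 libraries of 1 time and 0 of 4 of the other were few. For Sox9 they were Cyba, a subunit of the phagocyte NADPH oxidase, Scrib, a cell polarity gene, Fbxo6, a ubiquitin ligase subunit, and Glis2, a zinc finger factor of the kidney, at 10 days, and Sall3, another zinc finger factor, at 48 h. Only Cyba among them had a Sox9 peak of 2 or more steps, in 1 library. For H3K4me3 there were 49 at 10 days and 3 at 48 h. The 8 of the 10-day genes with the highest fold enrichment rank were Acnat1, Nova2, Vps37c, Smad5, a mediator of BMP signalling, Ctdnep1, Ubb, a ubiquitin gene, Mrpl55, a mitochondrial ribosomal protein, and Tbc1d14. The 48 h genes were St8sia2, a sialyltransferase, Slc5a8, a monocarboxylate transporter of the tubule, and Spesp1. Other splits of the 8 libraries of an antibody into 4 and 4 gave up to 16 genes for Sox9, against 5, and up to 80 for H3K4me3, against 52. In 1 simulation that dealt the peaks of an antibody at random to lists of the real lengths, the counts were 3 and 50. In 1 random draw of equal numbers of peaks, Sox9 had 0 such genes and H3K4me3 had 11, of which 6 at 10 days and 5 at 48 h. Leaving out 1 library loosens the rule, most for the time that loses it, since its genes then need a peak in fewer libraries. More Sox9 genes at 48 h without a 48 h library therefore do not show a turn of direction. There were 4 at 10 days and 20 at 48 h without 48h replicate 1, and 4 and 5 without 48h replicate 4.

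For Sox9, 4 regions were specific to 10 days and 0 to 48 h. They were chromosome 5, 115810035 to 115810443, in no gene, chromosome 11, 53478463 to 53478970, at Sowaha, chromosome 4, 131836937 to 131837348, at Ptpru, a receptor phosphatase gene, and chromosome 8, 123622267 to 123622738, in no gene. For H3K4me3, 18 were specific to 10 days and 7 to 48 h. The 10-day regions with the highest fold enrichment rank began at 31774138 on chromosome 13, 75438141 on chromosome 7, 147666590 on chromosome 3, 80676617 on chromosome 2 and 48747356 on chromosome 13. The 48 h regions began at 83318460 on chromosome 17, 88886222 on chromosome 10 (Slc5a8), 62281941 on chromosome 9 (Spesp1), 104177489 on chromosome 5 (Dspp) and 12992427 on chromosome 17 (Wtap). In 1 random draw of equal numbers of peaks there were more at 48 h for both antibodies. Sox9 then had 0 at 10 days and 1 at 48 h, and H3K4me3 had 1 and 7. The draw was not repeated for regions, so the direction is uncertain. Over 20 draws, H3K4me3 genes specific to 10 days numbered from 1 to 14. Under the looser rule without 1 library, Sox9 had 5 and 12 without 48h replicate 1, 7 and 7 without 48h replicate 2, and 4 and 6 without 48h replicate 4. That rule favours the time that lost a library, so these values do not show a turn of direction. Other splits of the libraries gave up to 15 regions for Sox9 and up to 34 for H3K4me3. At 4 against 4 libraries no single region can pass a Benjamini-Hochberg correction.

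Libraries of the same time did not resemble each other more than libraries of different times by more than chance. The mean base-pair Jaccard index was 1.013% within and 1.012% between times for Sox9, and 1.22% and 1.19% for H3K4me3 (exact permutation over 35 splits, one-sided p = 0.429 and p = 0.286).

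Sox9 and H3K4me3 peaks of a pellet overlapped more often than shifted peaks. At 10 days 2.97% ± 1.25 (SD, n = 4) of Sox9 peaks met an H3K4me3 peak of the same pellet and at 48 h 3.00% ± 0.804 (SD, n = 4), a difference within the spread (two-sided exact permutation p = 1). Among peaks of 2 or more steps the shares were 17.1% and 25.3% (exact permutation p = 0.286). In 1 random draw of equal numbers of peaks, not repeated, they were 1.51% and 2.57% (exact permutation p = 0.0571). Without 1 library these differences ranged from -12.0 to -4.22 points and from -1.32 to -0.792 points. By time it was 4.39 times that of shifted H3K4me3 peaks at 10 days and 6.61 times at 48 h (log2 difference -0.63, two-sided exact permutation p = 0.114; -0.84 to -0.37 without 1 library). Without 10d replicate 2 the exact permutation p was 0.0286, the smallest that 35 arrangements can give, for this ratio and for the equal draws. Over both times it was 5.50 times that of shifted peaks on average (range 2.42 to 9.32, above 1 in 8 of 8 pellets, exact sign-flip permutation p = 0.0078, the smallest that 8 pellets can give). Sox9 libraries also overlapped H3K4me3 libraries of other pellets of the same time 4.98 times as often as shifted peaks, against 5.18 times within the pellet (exact permutation over 576 pairings, p = 0.0938).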

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

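Every test of an explanation in this part was chosen after the pattern was seen, and for the material shared within a pellet, the background of both antibodies, the whole-step and random-placement tests of 1-step peaks and the splits of the libraries the measured values had been seen as well. By Dixon's test of the highest and the lowest of 4 values, which only a very distant library can pass, no library was set apart in 26 groups. The widest gaps were 0.817 of the group's range, for the gene-end share at 2 or more steps in H3K4me3 48h replicate 3, and 0.816, for the gene-end share in H3K4me3 10d replicate 1. The latter library also had 3052 genes with a peak of 2 or more steps, against 147 to 940 in the others of its group. Outside the chromosomes compared, the Sox9 lists held 115 peaks on the mitochondrial chromosome (5 to 21 per list). The H3K4me3 lists held 125 there (10 to 22 per list).

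Nearly every peak stood at 1 pileup step. Placement of these peaks evenly along the chromosomes is excluded, since 1-step summits lay at gene ends at least 1.54 times as often as shifted summits in each of the 16 lists, and up to 2.79 times. Background that itself favours gene ends is not excluded by shifted summits, and the inputs were not analysed. In every list at least 99.9898% of the solved peaks stood at whole steps and 0 lay between 1 and 2, which is what single fragments scaled up to the depth of a larger input would give; most peaks may therefore be single fragments. The read data were not used, so the fragments behind a peak were not counted. No biological explanation was tested.

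Sox9 and H3K4me3 peaks overlapped more often than shifted peaks. Material shared within a pellet is excluded as the whole cause, since lists of different pellets of a time overlapped 4.98 times as often as shifted peaks. A few regions present in almost every list are excluded too, since 4.13 times remained without the 89 regions in 14 or more of the 16 lists. Whether both lists hold the same background with no target of their own remains open: lists of the same antibody overlapped 1.04 times as much as lists of different antibodies, a small excess with an exact permutation p = 0.0078, the smallest that 128 swaps of the antibody within pellets can give, and binding of Sox9 at marked promoters was not tested. Sox9 lists overlapped each other 5.65 times as often as shifted peaks, H3K4me3 lists each other 4.51 times and lists of different antibodies 4.87 times. Without the 89 regions these values were 4.43, 4.07 and 4.13, and the ratio was 1.03 (exact permutation p = 0.0312). The test averaged both antibodies, and each antibody's own level of overlap enters its value. The excess can therefore not be assigned to either antibody, nor ruled out for H3K4me3. A peak in 5 or more H3K4me3 lists and at most 1 Sox9 list was present at 115 regions. The reverse held at 5 regions, with Sox9 lists being shorter on average. The gene-end share of H3K4me3, the positive control, over all peaks (8.56%) was not above that of Sox9 (8.70%). At 2 or more steps it was 20.3% against 15.4% (exact permutation p = 0.206).

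More H3K4me3 genes were specific to 10 days (49) than to 48 h (3). Longer lists at 10 days are a possible explanation. In 1 simulation, H3K4me3 peaks dealt at random to lists of the real lengths gave 50 genes specific to a time, against 52. List length alone thus sufficed for a count near the one observed, though the 50 were not divided by time. Over 20 random draws of 25811 peaks from each list, the mean was 5.6 genes at 10 days and 4.3 at 48 h. More were at 10 days in 10 draws and more at 48 h in 7. The time after injury stays open as a biological explanation for the difference in list length itself, which did not pass a permutation test.

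Chance cannot be excluded for the regions and genes specific to a time. For Sox9 regions, 28 of 35 splits of the 8 libraries gave as many (4, highest of the others 15), and for Sox9 genes 29 of 35 splits (5, highest of the others 16). For H3K4me3 regions it was 7 of 35 splits (25, highest of the others 34), and for H3K4me3 genes 6 of 35 splits (52, highest of the others 80).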

How the results depend on the processing

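Alternatives with peaks of 2 or more steps, random equal numbers of peaks or no recurrent genes, those leaving out pellets in the Sox9 against H3K4me3 share, and those of the random-list (sign flips included) and shifted-peak tests were chosen after the data were seen. Of 250 alternatives for 21 main results 169 gave the same call, with counts compared by size alone. No comparison of peak numbers, shares, overlap or gene lists between times passed under any of these. Leaving out Sox9 10d replicate 2 from the overlap with random equal numbers gave -1.32 points (exact permutation p = 0.0286). Unknown depth limits all counts; the Sox motif alternatives were not run, without a genome.

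Counts of regions specific to a time were 4 (Sox9) and 25 (H3K4me3). They became 0 and 5 with equal list length by p, 1 and 8 with random equal numbers, 1 and 2 at 2 or more steps, and 218 and 691 for at least 3 of 4 against at most 1 of 4. Leaving out 1 library, which loosens the rule, gave 9 to 29 and 42 to 136. Regions were more at 48 h in 1 draw of random equal numbers (1 to 0 and 7 to 1), and for Sox9 without 48h replicate 1 (12 to 5) or 4 (6 to 4). Leaving out a 48 h library itself favours 48 h in these counts, for regions and for genes. Counts of genes were 5 and 52. They became 0 and 0 with equal list length, 0 and 11 with random equal numbers, 0 and 0 at 2 or more steps, 42 and 115 with 3000 bp, 150 and 131 with the gene body and 10000 bp, and 9 to 61 and 74 to 225 without 1 library (Sox9 more at 48 h without 48h replicate 1, 20 to 4).

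Gene lists past the random-list test were 6 for Sox9 and 4 for H3K4me3. For Sox9 there were 0 with equal list length, 0 at 2 or more steps, 0 with random equal numbers, 1 against genes with an H3K4me3 peak (Wnt receptors and targets) and 1 without recurrent genes (Wnt ligands). The gene body gave 8, of which 3 were among the 6, without immediate early and stress genes (log2 odds ratio 0.06, adjusted permutation p = 0.943), the Sox family (0.0677) and the Hippo pathway (0.0625), and with cadherins, cartilage targets, kidney transcription factors, the Notch pathway and endothelium. For H3K4me3 there were 7 with the gene body (1 of the 4 among them), 1 against genes with an H3K4me3 peak, 1 with random equal numbers and 1 without recurrent genes. Equal list length and 2 or more steps also gave 4, of which 2 were among the 4, with Hippo pathway and housekeeping genes as the others. Without 10d replicate 1, 5 passed for Sox9 and 3 for H3K4me3, without hypoxia and glycolysis. Sign flips also gave 6 and 4, with housekeeping genes in place of the Sox family for Sox9 and fatty acid oxidation in place of hypoxia and glycolysis for H3K4me3. Enrichment at each time, 0 for both, became 1 (Sox9) and 11 (H3K4me3) with the gene body, and 0 to 3 for H3K4me3 without 1 library.

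Log2 peak number differences ranged from 0.50 to 1.35 for Sox9 and from 0.43 to 0.94 for H3K4me3 without 1 library, and were 1.18 and 1.15 at 2 or more steps. Differences turned in sign without passing a test. Agreement within minus between times turned for Sox9 to -0.0491 with equal list length and -0.669 at 2 or more steps (-0.0572 to 0.063 without 1 library), and for H3K4me3 to -0.0393 by the share overlapped over at least 50% of the peak (-0.0108 to 0.0588 without 1 library). The gene-end share, 10 days minus 48 h, turned to 0.37 points for Sox9 at 2 or more steps and to -0.0699 for H3K4me3 with 3000 bp (-0.201 to 0.652 without 1 library), and was 5.90 for H3K4me3 at 2 or more steps (-0.271 without 10d replicate 1). For Sox9 it ranged from -2.13 to -0.729 without 1 library. Sox9 minus H3K4me3 turned to -4.92 at 2 or more steps (-0.900 without pellet 10d 1), and with all peaks was -0.178 to 0.882 without 1 pellet. Overlap of Sox9 with H3K4me3, 10 days minus 48 h, was -8.25 points at 2 or more steps, -1.06 with random equal numbers (exact permutation p = 0.0571) and -0.615 to 0.366 without 1 library.

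Across times the replicate numbers share only a number: deviations correlated between -0.00725 and 0.00256 for Sox9 and between -0.0057 and 0.0107 for H3K4me3, and 0 of 4 and 1 of 4 were best with their own number. The replicate block left the differences at 1.00 and 0.70 for log2 peak number and -1.56 and 0.383 points for gene-end share, with exact permutation p from 0.25 to 0.75, where 4 pairs allow no p under 0.125, and changed no call. Paired by pellet, the Sox9 minus H3K4me3 share of 0.138 had p = 0.891 (exact permutation).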

Other observations

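The tests in this part were chosen after the data were seen, and H3K4me3 10d replicate 1 was singled out because it had the most peaks of 2 or more steps at gene ends. In that library 3052 genes, 13.9% of all, carried such a peak. They included 12 of 24 immediate early and stress genes (Fisher's exact test, adjusted p = 0.000697), among them the transcription factors Egr1, Fosb, Jun, Junb and Myc, the phosphatase gene Dusp1 and the stress gene Ddit3. They also included 10 of 24 housekeeping genes (Fisher's exact test, adjusted p = 0.0103), such as Gapdh and Eef2, and 9 of 22 hypoxia and glycolysis genes (adjusted p = 0.0146 by the same test), such as the glucose transporter gene Slc2a1, Pkm and Epas1. Of the immune cell list 1 of 25 genes was marked (C1qb), and of endothelium, stroma and mural cells, podocytes and parietal cells, Wnt ligands and cadherins none, but none of these lists passed Fisher's exact test (adjusted p from 0.355 to 0.584). Wnt receptors and targets (6 of 39) and the Sox family (3 of 19) were near the share of all genes. These p-values describe 1 library, since genes are not replicates.

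Genes marked in that library also carried peaks more often in the other lists. In the Sox9 lists 15.1% of marked and 9.15% of other genes had a peak at an end on average. The ratio lay between 1.44 and 2.01 (mean 1.71, above 1 in 8 of 8 lists, exact sign-flip permutation p = 0.0078, the smallest that 8 lists can give). In the other 7 H3K4me3 lists the ratio lay between 1.69 and 1.85 (mean 1.76, exact sign-flip permutation p = 0.0156). These ratios do not tell Sox9 binding at active promoters from cleavage of open chromatin.

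Merging all 16 lists gave 520204 regions, of which 37 had a peak in every list.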
